A study of Homo sapiens with 3 samples.

How the data were processed

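RNA of MHCC97H cells, a human hepatocellular carcinoma line, was measured on 3 Affymetrix arrays, 1 for each dose of hepatocyte growth factor (HGF): 0, 2 and 10 ng/ml. Total RNA was extracted with Trizol and turned into biotin-labelled cRNA with a 3' in vitro transcription kit, per the labels' protocols. The deposited values were log2 signals of 54675 probe sets per array, and MAS5, a program that summarises the probes of a probe set into 1 signal for each array separately, is named in the submitters' processing notes. Its version and settings were not given in the sources used here. Taken back to the linear scale, the deposited log2 values had a mean of 500 on each array after trimming 2% at each end, which is how MAS5 scales an array. No further scaling was applied. Each array was assigned to its dose by its label, and no value column was left unused.

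Gene names came from the platform annotation given for the probe sets. It gave 1 symbol for 41097 probe sets, several for 1801 and none for 11777, of which 62 were control probe sets. Of the probe sets with 1 symbol, 41043 were matched by gene identifier to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. Only probe sets with 1 symbol named a gene. No coordinates are given, because no build is named for the arrays.

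The floor was the median of all deposited values, 5.85 on the log2 scale or 57.9 in linear signal, and lower values were set to it. A gene was measured if a probe set of its own reached the floor on at least 1 array, which left 25305 probe sets of 13768 genes. Of these genes 6535 had more than 1 measured probe set. The probe set with the highest mean over the 3 arrays stood for the gene, chosen without regard to its difference between arrays. A gene was called higher or lower when the floored log2 values of 2 arrays differed by at least 1, that is 2-fold. With 1 array per dose there were 0 residual degrees of freedom, so this is a rule of size and no p-value was computed. A gene with the dimmer array below the floor has only a bound, written as at least N-fold.

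The genes named were fixed by a rule. For 10 against 0 and 2 against 0 ng/ml these were the 10 highest and the 10 lowest genes past the rule of size, and for 10 against 2 ng/ml the 5 highest and 5 lowest. Each had to be at or above the floor on both arrays and to reach the 75th percentile of all values (8.59 on the log2 scale) on the brighter array. All other measured probe sets of the gene had to differ with the same sign, and symbols of uncharacterised loci, non-coding RNAs and open reading frames were passed over. Genes with 1 measured probe set always met this sign rule. Up to 3 bounds per direction against 0 ng/ml, the 4 members of each gene list with the largest difference against 0 ng/ml, MET and HGF were added. The 27 gene lists covered pathways of HGF signalling, cell cycle, stress and liver identity, markers of other cell types, and array reference genes. Each list's median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean signal in 10 bins. The percentile describes these arrays and is not a p-value. The rules, the lists and all alternatives but 1 were chosen before the data were examined.

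Technical spread was read from the control probe sets and from the pair of the brightest and dimmest probe sets of each of 5413 genes with several at or above the floor on all 3 arrays. Because both comparisons against 0 ng/ml share 1 array, 100 simulated sets of 3 unchanged arrays were made for the overlaps. Their noise was drawn from the differences between the 10 and 2 ng/ml arrays, which hold any difference between these doses as well. The rule was also tested on simulated data for 10 against 0 ng/ml with 13171 genes. It recovered 48 of 50 genes raised by 1.5 (log2), 47 of 50 lowered by 1.5, and all 50 of those raised and of those lowered by 2.5. It also called 187 of 12951 unchanged genes (1.44%). A list of 20 genes shifted by 0.5 lay above all random lists. The raised, lowered and shifted genes were bright ones, with a mean more than 2 (log2) above the floor. All probe sets of a gene got the same change, and the noise again came from the 10 and 2 ng/ml arrays. The recovery therefore does not describe genes near the floor or genes whose probe sets disagree.

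The alternatives were a floor at the 25th or 75th percentile, no floor, median centring, quantile normalization, cyclic loess normalization, the mean difference over a gene's probe sets, and leaving out probe sets that match several transcripts or cross-hybridise. They used 2000 random lists each. The smallest difference among a gene's probe sets, 0 where their signs differed, was added after the data had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and cyclic loess was run with limma 3.58.1 in R 4.3.3. Probe sets with several symbols or none entered no comparison of genes. The number of arrays limits the precision of every value.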

Results

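Gene expression was measured in MHCC97H cells, a human hepatocellular carcinoma line, that had survived sublethal heat stress and were then kept in medium with 1% serum. The cells received hepatocyte growth factor (HGF), the ligand of the receptor tyrosine kinase MET, at 0, 2 or 10 ng/ml, and the stated purpose was to find classes of genes that were higher or lower among the 3 doses. Each dose had 1 array and no replicate, so no difference could be set against a spread between cultures, and none is given with a p-value. Of 54675 probe sets, 22866 named ones lay at or above the floor at 0 ng/ml, 23303 at 2 ng/ml and 22492 at 10 ng/ml. Across the 11782 genes above the floor on all arrays, the log2 signals correlated with r = 0.977 between 0 and 2 ng/ml, 0.984 between 0 and 10 ng/ml and 0.990 between 2 and 10 ng/ml. These correlations are across genes, which are not independent replicates.

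The control transcripts differed between the arrays in how well their 5' ends were represented. The ratio of 3' to 5' signal of GAPDH, a glycolytic enzyme, was 12.5 at 0 ng/ml, 1.26 at 2 ng/ml and 2.20 at 10 ng/ml. For ACTB, which encodes beta-actin, the ratio was 164, 12.2 and 55.2 in the same order. The bacterial transcripts added as labelling controls had the same order, with lys at 7.66, 1.34 and 1.89 and phe at 30.0, 3.56 and 14.8. The dap ratio was 7.38, 4.70 and 7.24, and the thr ratio was 11.3, 7.41 and 7.68. The 18 probe sets of the hybridisation controls were lower at 2 than at 0 ng/ml by a mean log2 difference of -0.50 ± 0.10 (SD over probe sets) and lower at 10 than at 0 ng/ml by -0.37 ± 0.08, and they differed by 0.13 ± 0.09 between 10 and 2 ng/ml.

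**Figure D1:**
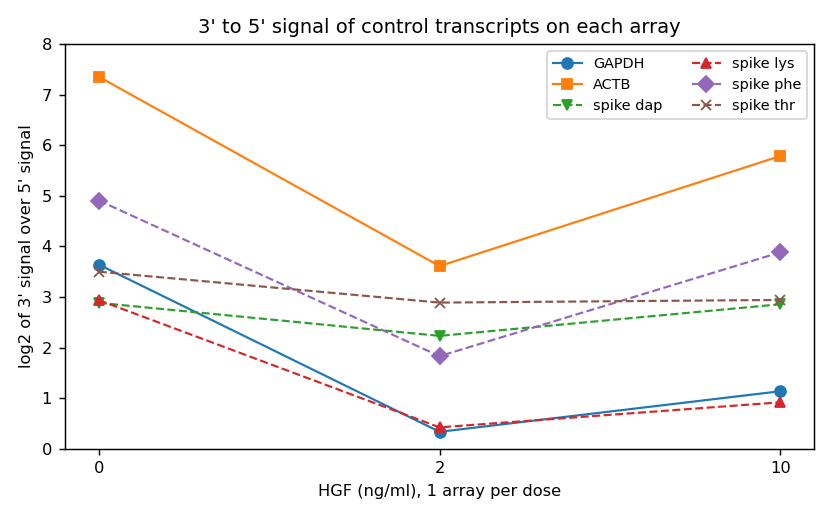
Log2 ratio of 3' to 5' signal (vertical axis) of GAPDH, ACTB and 4 added bacterial transcripts on the array of each HGF dose in ng/ml (horizontal axis); each point is 1 array. All 6 ratios shown were highest at 0 ng/ml and lowest at 2 ng/ml, from 164 to 12.2 for ACTB on the linear scale. At 0 ng/ml the 5' signals of lys, phe and thr were below the floor, and a second thr control, not shown, did not have this order.

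The comparison of 10 with 0 ng/ml asked which genes differed at the higher dose. BMP4, a secreted ligand of the bone morphogenetic protein family, was 5.14-fold higher at 10 ng/ml, with signals of 91.0, 298 and 468 at 0, 2 and 10 ng/ml. FOS, a subunit of the AP-1 transcription factor that is induced early by growth factors, was 3.04-fold higher, and ID1, an inhibitor of basic helix-loop-helix transcription factors, was 2.51-fold higher. FOS was named as a list member and was dim, with signals of 104, 293 and 316 at 0, 2 and 10 ng/ml on 1 measured probe set. CCN2, a matricellular protein induced by YAP and TGF-beta, was 2.29-fold higher, and OAS3, an interferon-induced enzyme, was 2.43-fold higher. Of 13768 genes, 90 were at least 2-fold higher and 127 at least 2-fold lower.

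Bright genes whose measured probe sets all agreed in sign, and that were highest at 10 against 0 ng/ml after BMP4, were SIAH2, an E3 ubiquitin ligase (3.54-fold), HNRNPF, a splicing regulator (3.27-fold), and SLC1A5, a glutamine transporter (2.90-fold). MMACHC, which processes vitamin B12, was 2.90-fold higher, the selenoprotein SELENOT 2.83-fold and the purinergic receptor P2RX4 2.77-fold. RAB14, a small GTPase of endosomal traffic, was 2.76-fold higher, the mitotic kinase AURKB 2.63-fold and the proteasome ATPase PSMC3 2.62-fold. Apart from BMP4 and MMACHC, these genes were all higher at 2 than at 10 ng/ml, as in the GAPDH and ACTB 5' signals. SELENOT had 1 other probe set, with a log2 difference of 0.08, and RAB14 had 2 others, at 0.007 and 0.75. BMP4 and the other genes named here had 1 measured probe set each, so agreement in sign could not fail for them.

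Among the genes lower at 10 ng/ml, CYP3A7-CYP3A51P, a readthrough transcript of the cytochrome P450 3A cluster, had a log2 difference of -1.94. Its probe set can cross-hybridise, as can those of KLC2 and OR7E47P below, so these genes are uncertain. MAN2B1, a lysosomal alpha-mannosidase, differed by -1.55, GPSM1, a modulator of G protein signalling, by -1.49, SASS6, a centriole assembly protein, by -1.43, and SNRNP48, a part of the minor spliceosome, by -1.40. SLC25A29, a mitochondrial carrier of basic amino acids, was lower by -1.36 (its other probe set by -0.11), the kinesin light chain KLC2 by -1.32, the zinc finger gene ZNF670 by -1.22 and the olfactory receptor pseudogene OR7E47P by -1.21. SEC62, which takes part in protein import into the endoplasmic reticulum, was lower by -1.19. Its other 3 probe sets were lower by -0.70 to -0.31, their sign being required by the rule for naming. Apart from SNRNP48, SLC25A29 and SEC62, these lower genes had 1 measured probe set each. MET itself had signals of 33972, 28364 and 26369 at 0, 2 and 10 ng/ml (log2 difference at 10 against 0 ng/ml -0.37). Its other 3 probe sets went the other way, by 0.63 to 1.31. HGF was near the floor, with signals of 127, 84.5 and 65.2 (-0.96).

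**Figure D2:**
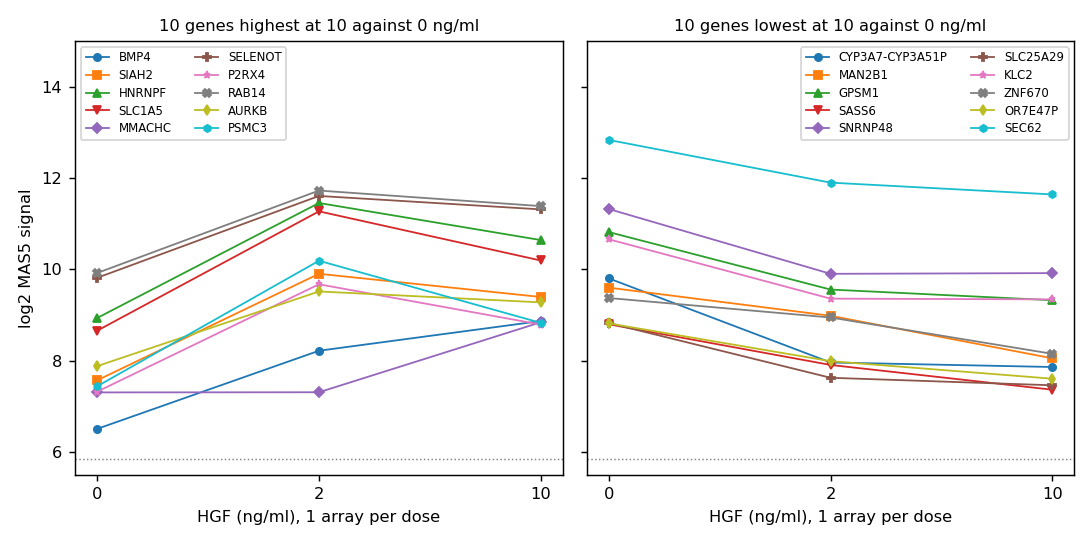
Log2 MAS5 signal (vertical axis) at each HGF dose in ng/ml (horizontal axis) of the 10 highest and 10 lowest bright genes with probe sets that agreed in sign, for 10 against 0 ng/ml; each point is 1 array and the dotted line is the floor at 5.85. BMP4 and MMACHC had their highest signal at 10 ng/ml and the other 8 genes on the left at 2 ng/ml. All genes shown but SELENOT, RAB14, SNRNP48, SLC25A29 and SEC62 had 1 measured probe set, so agreement in sign could not fail for them.

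The split of 90 higher and 127 lower genes (41.5% higher) moved with the scaling, to 88 and 142 (38.3%) under median centring, 109 and 109 (50%) under quantile normalization and 117 and 103 (53.2%) under cyclic loess. Simulated unchanged arrays gave a mean of 45.2 higher (32 to 67) and 46.2 lower (30 to 66) genes. Their noise came from the pair of arrays with the smallest spread, 2 and 10 ng/ml (SD 0.298, against 0.361 for 0 and 10 ng/ml and 0.434 for 0 and 2 ng/ml). In the other simulation, with known changes added, 187 of 12951 unchanged genes were 2-fold apart, against 217 of 13768 observed.

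At 10 against 0 ng/ml the medians of 4 gene lists lay outside the central 95% of matched random lists. The epithelial list, of junction and keratin genes, had a median log2 difference of 0.19 over 19 genes (percentile 99.8), with 0 members 2-fold higher or lower; KRT8 differed by 0.37, KRT7 by 0.36 and CDS1 by -0.60. This list lay outside in 7 of 9 alternatives. The list of ERK output and immediate early genes had a median of 0.12 over 24 genes (percentile 98.4), with FOS 2-fold higher (1.60), DUSP5, a phosphatase induced by ERK, at 0.77 and MYC at 0.63. It lay outside in 5 of 9, with a lowest median of 0.02 and a lowest percentile of 90.2. The NF-kB and inflammatory list had a median of 0.16 over 18 genes (percentile 98.6) and no member 2-fold apart; NFKB1 was at 0.62, NFKBIA at 0.56 and SOD2 at -0.64. It lay outside in only 4 of 9 alternatives, and as the smallest difference among probe sets its median was 0.00 (percentile 58.6). The ribosomal proteins had a median of -0.28 over 23 genes (percentile 0.160), 21 of them below 0, with RPL30 at -0.45 and RPL14 at -0.41 (on a cross-hybridising probe set, its other 2 at 0.22 and 0.28). The 18 hybridisation controls were lower by as much (-0.37), and so was the 3' probe set of GAPDH (-0.32). The ribosomal list lay outside in 7 of 9. Under quantile normalization the ribosomal median was -0.02, at percentile 49.7. With probe sets that match several transcripts or cross-hybridise left out, the epithelial median was -9.5e-05, and none of the 4 lists lay outside.

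The other lists lay inside the central 95% at 10 against 0 ng/ml. The HGF and MET axis had a median of -0.09 over 18 genes (percentile 44.6), with the receptor EGFR at 0.66 (its other 5 probe sets at -0.80 to 0.12) and the adaptor GAB1 at -0.80 (its other 5 at -0.04 to 1.31). Genes of invasion and pericellular proteolysis had a median of -0.06 over 19 genes (percentile 50.8), with the protease MMP7 at 0.54 and the integrin ITGB4 at -0.72. S phase and DNA replication had -0.14 over 26 genes (percentile 12.3), with the licensing factor CDT1 at -0.76 (on a cross-hybridising probe set, its other at 0.17), and G2 and mitosis had -0.00 over 28 genes (percentile 77.8), with AURKB 2-fold higher (1.40) and CDK1 at 0.56. The p53 targets and CDK inhibitors had -0.10 over 16 genes (percentile 35), with CDKN1A at 0.79. Autophagy had 0.07 over 35 genes (percentile 95.8), with MAP1LC3A at -0.71 (its other 2 probe sets at 0.00 and 0.09) and the kinase ULK1 at 0.42. The heat shock list had -0.13 over 21 genes (percentile 15.6), with the co-chaperone STIP1 at 0.72. The list of unfolded protein and amino acid stress had 0.07 over 24 genes (percentile 93.9), with HSP90B1, a chaperone of the endoplasmic reticulum, 2-fold higher (1.75) but its other probe set at -0.21. The mesenchymal list had -0.12 over 18 genes (percentile 25.5), with VIM at 0.67 and CDH2 at -0.57 (its other probe set at 1.51). The hepatocyte list had 0.05 over 20 genes (percentile 92.2), with TTR, a plasma transport protein, 2-fold higher (1.19) and ALB at 0.61 (its other probe set at 0.00).

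Liver cancer stem cell markers had a median of -0.04 over 8 genes (percentile 50.7), with SOX9 at 0.60. The interferon response had 0.02 over 18 genes (percentile 81.6), with OAS3 2-fold higher (1.28) and its other probe set at 0.13. Hypoxia and glycolysis had -0.10 over 17 genes (percentile 33.4) and cholesterol synthesis -0.13 over 14 (percentile 18.2), with INSIG1 at -0.78 (its other 2 probe sets at 0.32 and 1.41) and SQLE at 0.70 (its other 3 at 0.00 to 1.78). The anti-apoptotic list had -0.04 over 8 genes (percentile 52.4) and the pro-apoptotic list -0.14 over 12 (percentile 22.8), with BIK at -0.58. NRF2 and metal stress had -0.25 over 15 genes (percentile 3.42), 13 of them below 0, with HMOX1 at -0.47 and MT1E at -0.52. YAP and TGF-beta targets had 0.01 over 16 genes (percentile 70.6), with ID1 (1.33) and CCN2 (1.19) 2-fold higher and ID3 at 0.66. WNT targets had 0.05 over 7 genes (percentile 82.2), with AXIN2 at 0.44 (its other probe set at -0.12). Of the markers of other cell types, stellate cell and fibroblast genes had 0.00 over 7 (percentile 71.3), immune cell genes -0.04 over 8 (percentile 46.2) and endothelial genes -0.22 over 3 (percentile 27.1). The array reference genes had -0.21 over 12 genes (percentile 6.47), with TFRC at -0.38 (its other 2 probe sets at 0.00 and 0.34).

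**Figure D3:**
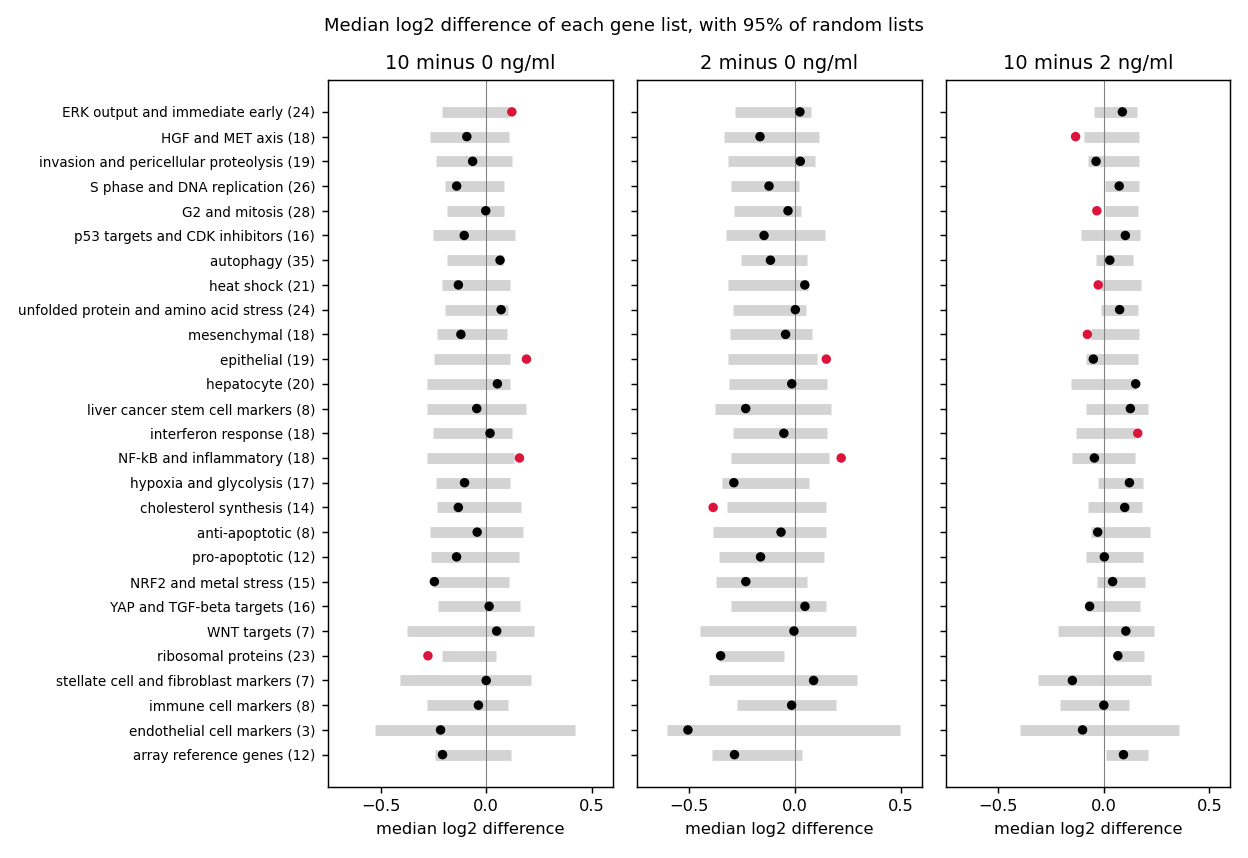
Median log2 difference (horizontal axes) of each of the 27 gene lists (vertical axis, measured genes in parentheses) for the 3 comparisons; grey bars span 95% of 10000 matched random lists, and red points lie outside them. There were 12 red points among 81, where 4.05 would lie outside by the width of the bars.

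The comparison of 2 with 0 ng/ml asked which genes differed at the lower dose. PSMC3, the proteasome ATPase, was 6.73-fold higher at 2 ng/ml, the glutamine transporter SLC1A5 6.12-fold and the splicing regulator HNRNPF 5.73-fold. ID1 was 3.74-fold higher, and of the other YAP and TGF-beta targets CCN2 was higher by 1.37 (log2) and ID2 by 1.13. FOS was 2.82-fold higher, on dim signals of 104 at 0 ng/ml and 293 at 2 ng/ml. The metallothionein MT1E, which binds zinc and copper, was lower with a log2 difference of -1.40, and its other probe set differed by -1.09. The probe sets of MT1E, PCGF2, KLC2, KRT8, CALR and MAP1LC3A can cross-hybridise, so these genes are uncertain. In all, 232 genes were at least 2-fold higher and 177 at least 2-fold lower. On this array the 5' control signals of GAPDH and ACTB were also higher, by 2.95 and 3.42.

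Among genes above the floor on both arrays that met the rule for naming, HSP90B1 was the highest at 2 against 0 ng/ml. It was 8.79-fold higher, on a probe set that can cross-hybridise, and its other probe set differed by 0.64. CTSLP8, a cathepsin pseudogene whose probe set can also cross-hybridise, was 7.17-fold higher. P2RX4 was 5.11-fold higher, SIAH2 5.04-fold, the nicotinic receptor subunit CHRNA5 4.46-fold and CNOT8, a subunit of the CCR4-NOT deadenylase, 3.75-fold. MPDU1, needed for the use of dolichol-linked mannose in glycosylation, was at least 13.0-fold higher, with a signal of 26.4 at 0 ng/ml, below the floor, and of 753 at 2 ng/ml. Lower genes were CYP3A7-CYP3A51P (-1.84), the WNT antagonist NKD2 (-1.52), SNRNP48 (-1.42), the Polycomb gene PCGF2 (-1.37), the adaptor subunit AP1G2 (-1.31) and KLC2 (-1.30). MICB, a stress-induced ligand of the receptor NKG2D, differed by -1.27, the dehydrogenase D2HGDH by -1.26 and GPSM1 by -1.26. The other 3 probe sets of PCGF2 were lower by -1.44 to -0.76, their sign being required by the rule for naming.

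MET differed by -0.26 at 2 against 0 ng/ml, while its other 3 probe sets were higher by 1.21 to 3.78. Its difference was 0.07 under quantile normalization and 1.77 as the mean over its probe sets. HGF differed by -0.59. The split of 232 higher and 177 lower genes (56.7% higher) turned to 180 and 268 (40.2%) under median centring and 188 and 241 (43.8%) under quantile normalization, and was 211 and 195 (52.0%) under cyclic loess. As the mean over a gene's probe sets it was 324 and 123 (72.5%). Simulated unchanged arrays gave a mean of 46.7 higher (28 to 68) and 45.9 lower (25 to 67) genes. Their noise came from the 2 and 10 ng/ml arrays (SD 0.298), a closer pair than 0 and 2 ng/ml (SD 0.434). An excess over these counts therefore does not separate a response from the wider spread. The other simulation, made for 10 against 0 ng/ml, called 187 of 12951 unchanged genes, and why it called more was not tested.

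At 2 against 0 ng/ml 3 lists lay outside the central 95% of random lists. The NF-kB and inflammatory list had a median of 0.22 (percentile 99.1), with NFKB1 at 0.97 and NFKBIA at 0.63, and no member 2-fold apart. It lay outside in 6 of 9 alternatives. The epithelial list had a median of 0.15 (percentile 98.8), with KRT8 (1.32) and KRT7 (1.13) 2-fold higher and CLDN1 at -0.78 (its other probe set at 0.28). It lay outside in 6 of 9, and at percentile 96.6 under quantile normalization. Cholesterol synthesis had a median of -0.39 (percentile 0.600), 11 of 14 genes below 0, with NSDHL at -0.84 and SQLE at 0.67 (its other 3 probe sets at -0.19 to 2.87), and lay outside in 6 of 9. As the mean over each gene's probe sets, the cholesterol median was 0.08, and the other probe set of NSDHL was at 0.83. With shared and cross-hybridising probe sets left out, none of the 3 lists lay outside.

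Inside the central 95% at 2 against 0 ng/ml, ERK output had a median of 0.02 (percentile 91.5), the HGF and MET axis -0.17 (percentile 33.1), invasion 0.02 (percentile 89.7) with MMP2 at -0.96 (its other probe set at 0.11), and S phase -0.12 (percentile 57.1) with FEN1 at -0.75 (its other probe set at 1.39). G2 and mitosis had -0.03 (percentile 88.8) with AURKB 2-fold higher (1.64), p53 targets -0.15 (percentile 33.9), and autophagy -0.12 (percentile 41.0) with MAP1LC3A 2-fold lower (-1.02) and its other 2 probe sets at 0.45 and 0.78. Heat shock had 0.05 (percentile 96.5), with STIP1 2-fold higher (1.27) and HSPA1L at least 2.03-fold lower, its signal of 49.3 at 2 ng/ml being below the floor. The unfolded protein list had 0.00 (percentile 91.1), with HSP90B1 2-fold higher and the chaperone CALR 2-fold lower (-1.10) but its other 2 probe sets at -0.41 and 0.06. The mesenchymal list had -0.04 (percentile 72.4) with VIM 2-fold higher (1.04), while CDH2 was at -0.75 and its other probe set at 2.57. The hepatocyte list had -0.02 (percentile 73.7) with TTR 2.37-fold higher, stem cell markers -0.23 (percentile 18.5) and the interferon response -0.05 (percentile 56.8), with OAS3 (1.36) 2-fold higher, its other probe set at -0.03, and IRF7 2.01-fold lower.

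Hypoxia and glycolysis had a median of -0.29 (percentile 7.59) at 2 against 0 ng/ml, with SLC2A1 at -0.79. The anti-apoptotic list had -0.07 (percentile 65.7), the pro-apoptotic list -0.16 (percentile 34.8) with BMF at 0.89, and NRF2 and metal stress -0.23 (percentile 24.7) with MT1E 2-fold lower. YAP and TGF-beta targets had 0.05 (percentile 86.2) with ID1, CCN2 and ID2 2-fold higher, WNT targets -0.01 (percentile 66.7), and ribosomal proteins -0.35 (percentile 3.71) with 21 of 23 below 0. Stellate cell and fibroblast genes had 0.09 (percentile 83.2), immune cell genes -0.02 (percentile 50.6), endothelial genes -0.51 (percentile 5.28) and array reference genes -0.29 (percentile 16.9).

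The comparison of 10 with 2 ng/ml asked how the doses with HGF differed. MMACHC was 2.89-fold higher at 10 ng/ml and CEMIP, which takes part in hyaluronan breakdown, 2.02-fold; no other higher gene met the rule for naming. Lower at 10 ng/ml were MPDU1 (-1.87), the transcription factor DEAF1 (-1.83), the endosomal protein ENTR1 (-1.57), HSP90B1 (-1.38) and PSMC3 (-1.36). In all, 46 genes were at least 2-fold higher and 99 at least 2-fold lower (31.7% higher), against 57 and 74 (43.5%) under median centring, 67 and 64 (51.1%) under quantile normalization and 61 and 70 (46.6%) under cyclic loess. The 5' control signals of ACTB and GAPDH were also lower at 10 than at 2 ng/ml, by -2.08 and -0.77. This comparison therefore shared the difference in 5' signal. That of 18S ribosomal RNA was lower by -1.72, but its 3' and middle signals were lower too, by -0.80 and -1.01. For the probe set pairs of a gene, the difference of the dimmer minus that of the brighter had a median of -0.19, but their positions were not used.

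For 10 against 2 ng/ml 5 lists lay outside the central 95%. The interferon response had a median of 0.16 (percentile 98.3), with MX1 signals of 128, 126 and 220 over the doses, but it lay outside in only 4 of 9 alternatives. Its percentile was 94.9 under quantile normalization, and its median was 0.00 (percentile 54.5) as the smallest difference among probe sets. The HGF and MET axis had -0.13 (percentile 0.690), outside in 5 of 9, with a median of 0.00 (percentile 48.3) as the smallest difference. G2 and mitosis had -0.03 (percentile 0.260) and heat shock -0.03 (percentile 1.28), each outside in 8 of 9, and the mesenchymal list -0.08 (percentile 1.35), outside in 5 of 9. Under median centring the medians of G2 and mitosis (0.05), heat shock (0.05) and the mesenchymal list (0.003) were above 0, the last at percentile 3, while random lists also had medians above 0. With shared and cross-hybridising probe sets left out, none of the 5 lists lay outside.

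The other medians for 10 against 2 ng/ml were 0.09 for ERK output (percentile 68.4), -0.04 for invasion (percentile 7.46), 0.07 for S phase (percentile 33.1), 0.10 for p53 targets (percentile 81.6) and 0.03 for autophagy (percentile 26.0). They were 0.07 for the unfolded protein list (percentile 46.2) with HSP90B1 2-fold lower, -0.05 for the epithelial list (percentile 7.02), 0.15 for the hepatocyte list (percentile 97.49, just inside), 0.13 for stem cell markers (percentile 79.9) and -0.04 for NF-kB (percentile 27.0). Hypoxia had 0.12 (percentile 76.6), cholesterol synthesis 0.10 (percentile 73.1), the anti-apoptotic list -0.03 (percentile 6.05) and the pro-apoptotic list 0.00 (percentile 20.4) with BMF 2-fold lower (-1.29). NRF2 had 0.04 (percentile 18.6), YAP and TGF-beta targets -0.07 (percentile 4.71), WNT targets 0.10 (percentile 77.1) and ribosomal proteins 0.07 (percentile 4.15). Stellate cell and fibroblast genes had -0.15 (percentile 14.7), immune cell genes 0.00 (percentile 61.1), endothelial genes -0.10 (percentile 29.0) and reference genes 0.09 (percentile 32.7).

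The classes of genes over the 3 doses were formed from the 582 genes whose highest and lowest values were at least 2-fold apart. The highest signal was at 2 ng/ml for 265 genes (45.5%), PSMC3, SLC1A5, HNRNPF and ID1 among them, and the lowest at 2 ng/ml for 170 (29.2%), such as MT1E and NKD2. Signals were ordered upward with dose for 27 genes (4.64%), with BMP4 and MMACHC, and downward for 101 (17.4%), with MAN2B1, GPSM1 and SEC62; 19 had ties at the floor. The highest and lowest counts at 2 ng/ml turned to 196 and 261 under median centring and 193 and 249 under quantile normalization, and were 221 and 197 under cyclic loess. Arrays that differed by exchangeable noise alone would give 33.3%, 33.3%, 16.7% and 16.7%. The 0 ng/ml array stood farthest from the middle value for 288 genes (49.5%), the 2 ng/ml array for 189 and the 10 ng/ml array for 105.

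Of the genes at least 2-fold from 0 ng/ml, 63 were higher at both doses, ID1, FOS, SLC1A5 and AURKB among them, and 35 were lower at both, such as GPSM1, KLC2 and SNRNP48; 0 went in opposite directions. Simulated unchanged arrays sharing the 0 ng/ml array gave a mean of 8.24 (3 to 18) and 9.79 (3 to 17), and independent lists of these sizes would share 1.52 and 1.63. The log2 differences of both comparisons correlated across genes with r = 0.712 (simulated 0.499) and a covariance of 0.116 (simulated 0.0410). The simulated noise came from the 2 and 10 ng/ml arrays, so it held no shift particular to the 0 ng/ml array, such as its weaker 5' signal. The single 0 ng/ml array cannot be divided, so part or all of the excess may come from it. Of the 232 genes higher at 2 ng/ml, 207 (89.2%) lay between 0 and 2 ng/ml at 10 ng/ml, against a simulated mean of 80.7% (63.5% to 93.5%).

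Probe sets of the same gene differed in what they showed. Over 5413 genes with several probe sets above the floor on all arrays, the differences of the brightest and the dimmest correlated across genes with r = 0.025 for 2 against 0 ng/ml, 0.051 for 10 against 0 and 0.077 for 10 against 2. The SD within a gene was 0.585, 0.429 and 0.344 in the same order. Of the 409 genes 2-fold apart between 2 and 0 ng/ml, 143 had another measured probe set, which had the same sign throughout in 63 and was itself 2-fold apart in 18. For 10 against 0 ng/ml these were 64, 27 and 2 of 217 genes.

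**Figure D4:**
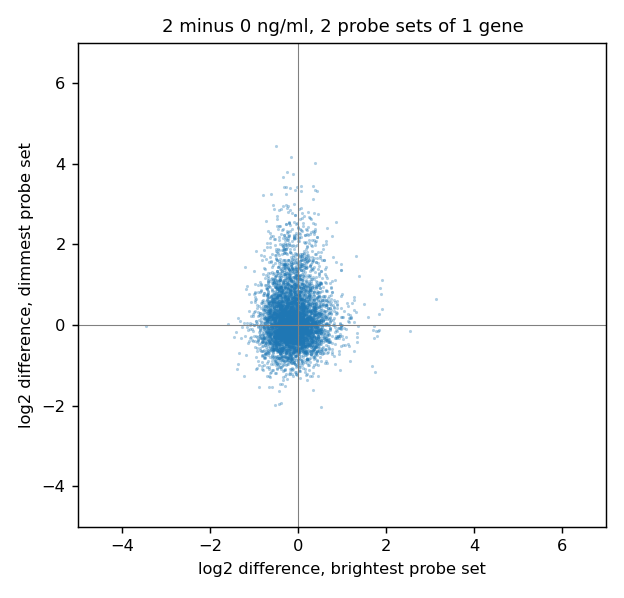
Log2 difference between 2 and 0 ng/ml of the dimmest (vertical axis) against the brightest (horizontal axis) probe set of 5413 genes with several above the floor on all arrays; each point is 1 gene. The dimmest probe sets spread further (SD 0.729) than the brightest (SD 0.410), mostly upward.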

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

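The tests of 5' recovery, of growth with dose, of dim signal, of the probe set pairs after cyclic loess, and of lower genes on other kinds of probe set were chosen after the results were seen, and the test of the share of cross-hybridising probe sets after cyclic loess was chosen after the excess was seen but before its own value was.

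Some 5' control probe sets, outside the gene comparisons, were higher than at 0 ng/ml, while the 18 hybridisation controls were lower. The 5' probe set of GAPDH was higher by 2.95 (log2) at 2 ng/ml and 2.18 at 10 ng/ml, that of ACTB by 3.42 and 1.34, and that of 18S ribosomal RNA by 1.95 at 2 ng/ml but 0.23 at 10 ng/ml. The 3' and middle probe sets of 18S ribosomal RNA were higher at 2 than at 0 ng/ml as well, by 0.75 and 1.26, so its difference was not confined to the 5' end. Among probe sets with no single gene name, which the gene comparisons left out, 210 of 5346 were at least 2-fold higher at 2 than at 0 ng/ml and 90 lower, and 89 were higher at 10 than at 0 ng/ml and 82 lower.

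Genes such as SLC1A5, HNRNPF and PSMC3 were higher at 2 than at 0 ng/ml with 10 ng/ml in between, the order of the 5' control signals. An intensity trend left by the scaling is argued against as the whole cause, since 211 genes were 2-fold higher at 2 ng/ml after cyclic loess, against 232. Under quantile normalization 188 were higher and 241 lower, so the excess of higher over lower genes did depend on the scaling. Weaker recovery of 5' ends at 0 ng/ml could give the pattern. Over all pairs the difference of the dimmer probe set of a gene exceeded that of the brighter one by a median of 0.236, and by 0.194 after cyclic loess. Reading this as 5' recovery assumes that dimmer probe sets lie farther from the 3' end, which was not tested. The positions of the members' probes were not used here, so 5' recovery was not decided for them. Growth with dose was looked for among the 90 genes 2-fold higher at 10 than at 0 ng/ml, 63 of them also 2-fold higher at 2 ng/ml. Of the 90, 34 were higher at 10 than at 2 ng/ml. With the floor at the 75th percentile it was 2 of 26, and at the 25th 593 of 814. Genes with 10 ng/ml in between are lower at 10 than at 2 ng/ml by definition, so this decides nothing for them. A response to HGF that was strongest at 2 ng/ml stays open, untested, since 1 array per dose confounds it with 5' recovery.

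Probe sets of the same gene hardly shared their difference between 2 and 0 ng/ml, as for MET, CDH2 and CDK1. Dim signal as the cause is argued against by r = -0.00119 where both probe sets were bright (2749 genes), and an intensity trend by r = 0.0456 after cyclic loess. Unequal recovery of 5' ends could also set the probe sets of a gene apart, but without probe positions it was not tested here. The difference of the dimmer probe set exceeded that of the brighter one by a median of 0.236 over all pairs. Where both were bright it did so by 0.298. No biological explanation, such as other transcript ends, was tested either.

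Genes lower at 10 than at 0 ng/ml sat on cross-hybridising probe sets more often (23 of 127, 18.1%) than genes within 2-fold (6.36%), as did those lower at 2 than at 0 ng/ml (14.1%) and at 10 than at 2 ng/ml (16.2%). That the other 104 had probe sets of another kind restates this and says nothing of its cause. An intensity trend is argued against as the whole cause, since after cyclic loess 103 genes were 2-fold lower and 19.4% of them (exact binomial 95% interval 12.3 to 28.4%) had such probe sets. With the floor at the 25th percentile the share was 6.86% (5.41 to 8.57%), against 5.67% of genes within 2-fold. Why the excess arose stays open, as does a response to HGF, which 1 array per dose cannot test.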

How the results depend on the processing

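The smallest difference among a gene's probe sets was the alternative chosen after seeing the data; it gives no dose classes. No paired analysis was possible because each dose had 1 array, and no array could be left out of a dose. Signal over the floor limited the counts most. With the floor at the 25th percentile, 814 genes were higher and 1049 lower at 10 against 0 ng/ml, 1021 and 1010 at 2 against 0, and 674 and 886 at 10 against 2; dose classes held 386 genes rising with dose, 613 falling, 1184 highest at 2 and 879 lowest at 2. With the floor at the 75th percentile these were 26 and 16, 86 and 44, 2 and 10, then 2, 13, 88 and 41. Without a floor they were 375 and 552, 579 and 534, 288 and 468, then 161, 378, 642 and 497. These floors left 18217 and 8655 genes, while without a floor the 13768 genes were tested, so fewer or more genes are not the cause there. Median centring gave 268 genes lower at 2 than at 0 ng/ml and 261 lowest at 2. Quantile normalization gave 64 lower at 10 than at 2 and 43 rising, and cyclic loess 44 rising. The mean over probe sets gave 113 lowest at 2, and the smallest difference gave 115 lower at 2 than at 0 and 64 lower at 10 than at 2. For these the cause was not tested.

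Of the other counts, 32 of genes and 16 of dose classes stayed within 1.5 times. Of list medians 582 moved by less than their error and 139 by more, and of the 12 outside 95% of random lists 5 values changed sign: for 10 against 2 ng/ml under median centring G2 and mitosis (0.0475), heat shock (0.0539) and mesenchymal (0.00255), cholesterol synthesis at 2 against 0 as the mean over probe sets (0.0805), and epithelial at 10 against 0 without shared probe sets (-9.5e-05). MAP1LC3A at 2 against 0 ng/ml was 0.0705 as the mean over probe sets, and CALR was 0.0597 without shared probe sets. Of 69 named differences of at least 2-fold, 68 stayed 2-fold under each of the 3 scalings, 55 as the mean over probe sets, 51 as the smallest difference, 36 of 64 with the higher floor and 32 of 36 without shared probe sets. For a gene with 1 measured probe set, the mean and the smallest difference equal the main value. The counts of 55 and 51 therefore hold genes that could not change. Of those 12 list medians, the ones of G2 and mitosis and of heat shock at 10 against 2 ng/ml stayed outside in 8 of 9 alternatives, the most of any. With shared and cross-hybridising probe sets left out, none of the 12 lay outside. That setting left 10623 of the 13768 genes, and G2 and mitosis moved only to percentile 3.2, just inside. Dependence on such probe sets was therefore not separated from the loss of genes.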

Other observations

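The genes in the next paragraph were chosen after their values were seen; the test of BMP targets was set before its result.

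A small group of bright genes was ordered by dose, with all measured probe sets in the same direction from 0 to 10 ng/ml. Apart from IDNK and SLX9, the genes ordered upward had 1 measured probe set, as had most ordered downward. Agreement in direction could not fail for these. Upward there were 8, and besides BMP4 and MMACHC they were RFXANK, a regulator of MHC class II genes (186, 305 and 415 in signal at 0, 2 and 10 ng/ml), the transporter ABCA4 (207, 402 and 454), the kinase IDNK (342, 450 and 710), SLX9, a ribosome biogenesis factor (263, 300.5 and 539), the Mediator subunit MED10 (921, 1789 and 1868) and PPARG, a nuclear receptor of lipid metabolism (2138, 4052 and 4302). Downward there were 18. SEC62 went from 7328 to 3831 and 3203, PHIP from 2362 to 1476 and 1139 (3 probe sets), CEP295, a centriole protein, from 788 to 482 and 373, and HBB, the beta-globin gene, from 444 to 282 and 201 (4 probe sets). The probe sets of SLX9 and HBB can cross-hybridise. MMACHC, IDNK and SLX9 had more of their difference between 2 and 10 ng/ml, by 1.53, 0.66 and 0.84 on the log2 scale, than between 0 and 2 ng/ml.

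BMP4, ID1, ID2 and ID3 were all higher at 2 and 10 than at 0 ng/ml (the other probe set of ID2 at -0.12 at 10 ng/ml), and the ID genes are targets of BMP signalling. From 2 to 10 ng/ml they parted. The BMP4 signal went from 298 to 468, but ID1 from 4974 to 3337, ID2 from 2367 to 1647 and ID3 from 2078 to 1862. The ID genes thus had the order of the 5' control signals. One hypothesis is that BMP output as a whole was higher. Of 10 other measured BMP targets, 0 were higher by 0.5 (log2) or more at 10 ng/ml; 7 of them were below 0, with ID4 at -0.91, DLX2 at -0.38 and ATOH8 at -0.30, and BAMBI was the highest at 0.32. Their median was -0.13, at percentile 32.8 of matched random lists, so this test gave no sign of a wider BMP response from 0 to 10 ng/ml. For 2 against 0 ng/ml the median was -0.30 (percentile 8.10), and for 10 against 2 ng/ml it was 0.18 (percentile 95.8), with 8 of 10 above 0. ID4 and DLX2 were dim, with signals of 126 and 108 at 0 ng/ml, and the probe set of ID4 can cross-hybridise.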
